A study of Homo sapiens with 6 samples.

How the data were processed

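RNA sequencing libraries of MCF-7 cells transfected with siControl or siPSMD14 were compared, 3 libraries per group, with groups and replicate numbers taken from the sample titles. Cells were grown in 12-well plates, RNA was taken with Trizol, and libraries were made with the BGISEQ-500 protocol, per the labels. The labels do not say that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The authors deposited 1 table per library with a gene symbol and a value, taken here as FPKM. No header names that unit. It was inferred from the values, because at low values in genes with 1 annotated transcript the value times the transcript length lay near whole multiples of 1 constant per library, between 47.3 and 49.1. A value counted as near a whole multiple within 0.2, which held for 59.0% to 64.8% of 254 to 276 values per library, where a uniform spread gives 40%. The constant was chosen to fit these same values best, which raises that share. Such spacing would also hold for other units scaled by length and depth, so it cannot tell FPKM from those. With FPKM as the unit, these constants gave depths of 20370000 to 21140000 fragments. The reads were processed against GRCh38, per the submitters' processing notes, and the aligner, the counting tool and the annotation are not given in the sources used here. The labels do not say whether the libraries kept strand, so overlapping antisense genes were not separated.

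The 6 tables held the same 18081 symbols in the same order and were joined by position. In the first column, 25 symbols had been turned into dates by spreadsheet software and 76 entries in all were plain numbers. These were tested under their position but never named. Squared differences between replicates of a group were 2.73 to 5.88 times those of counting noise at those inferred depths. No table was thus a copy of another. The constants behind the depths were sought only within a set range, and a lower true depth would shrink this ratio. It therefore argues against a second sequencing of the same library only if the inferred depths hold. Separate libraries of 1 culture are not excluded by it. Values were used as log2(FPKM + 1) without further scaling. Genes at 1 FPKM or more in at least 3 libraries were kept, which left 11867.

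The comparison was fitted with limma 3.58.1 in R 4.3.3, with group as the only term and a mean-variance trend. P-values were two-sided and Benjamini-Hochberg adjusted over all tested genes, with a threshold of 0.05. SE is the moderated standard error of limma. PSMD14 and ESR1 also had an exact permutation test. For changes given without a p-value, genes said to have risen or fallen had passed this threshold. The design was fixed before the data were examined, with FPKM as the assumed unit, and no count model was used because the values are not counts.

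Gene lists for 33 pathways, complexes and cell types were also fixed before the data were examined, and 32 had at least 3 tested genes. The list of mitochondrially encoded genes had none and was not analysed here. Lists were tested with camera of limma at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 32 lists. Camera compares the genes of a list with all other tested genes. Of the 32 lists, 15 passed, 10 upward and 5 downward, and none passed with an estimated correlation. The rotation test fry asks whether the genes of a list moved on balance in 1 direction without comparing them with other genes, and 29 lists passed it. Its mixed form asks for changes in either direction, and 32 passed. List members were counted over all tested genes and with p-values adjusted over the list alone.

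The genes named were chosen by a rule fixed before the data were examined. They were PSMD14 and ESR1, and the 10 largest rises and 10 largest falls with adjusted p under 0.05, no overlap between the 3 and 3 libraries and a mean of at least 5 FPKM in the higher group, leaving out symbols that start with LOC. From each list that passed came the 3 members with the smallest p, and from each other list at most 2. TFF1, GREB1, PGR, CCND1 and MYC were named whatever their values. PSMD7 was named after its value was seen, as the smallest rise of its list.

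Transcript lengths, GC content, 3' UTRs and coordinates came from GENCODE 29 on GRCh38, using for each symbol the protein-coding transcript with the longest coding part. A length was found for 98.7% of tested genes. For words of 7 bases, each of 16384 words was scored over 11294 tested genes with a 3' UTR of at least 50 bases. The score z was the mean residual log2 change of the genes holding the word, in units of its sampling error, after regression on transcript length, GC content, 3' UTR length and 3' UTR GC content. Chance values came from 100 permutations of the residuals over genes. The scan used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots used matplotlib 3.10.9.

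The fit was tested on simulated data with the means of the real genes and 200 changed genes among 11745 tested. The spread of each gene was read from a smooth curve of spread against level, with independent normal noise. Genes of like level thus had the same spread, and no trend with length was simulated. The rates that follow may therefore be too favourable for the real data, where 7461 genes changed. Changes of 0.25, 0.5, 1 and 2 on the log2 scale were recovered in 44%, 100%, 98% and 100% of 50 genes each, and 5.52% of calls were false. In 20 simulated data sets with no change, 2.85% of camera p-values at the preset correlation were under 0.05, and 0.475% with an estimated correlation. Those data had no correlation between genes, so they do not test what correlated lists do.

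The alternatives tried were a pseudocount of 0.1, no filter, a filter at 5 FPKM, quantile normalization, median-ratio scaling, limma without the trend and with robust variances, the replicate number as a block, each library left out in turn, and a minimum change of 2-fold. Further alternatives, named in the closing part, were chosen after the data were seen.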

Results

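Gene expression was measured by RNA sequencing in MCF-7 cells, an established human breast cancer line that carries estrogen receptor alpha (ERα). The cells had been transfected with a control siRNA (siControl) or an siRNA against PSMD14 (siPSMD14), and each group had 3 libraries. An siRNA is a short double-stranded RNA that lowers the level of a messenger RNA with a matching sequence. PSMD14 is a deubiquitinase of the 19S regulatory particle of the proteasome, where it removes ubiquitin chains from proteins that are about to be degraded. The title of the series sets the comparison in the question of how PSMD14 acts on ERα and estrogen signalling. If the unit is FPKM, the spacing of the low values gave depths of 20370000 to 21140000 fragments. Each library listed 18081 genes, with totals between 464303 and 532258 FPKM. Of these genes, 11867 reached 1 FPKM in at least 3 libraries and were tested. Changes are given as siPSMD14 against siControl on the log2(FPKM + 1) scale, which understates the change of genes near or below 1 FPKM.

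PSMD14 itself fell from 51.2 ± 4.60 FPKM in siControl to 4.99 ± 1.08 FPKM in siPSMD14 (SD, n = 3 libraries per group). Its 3 siControl libraries held 48.5, 48.5 and 56.5 FPKM, and its 3 siPSMD14 libraries 4.38, 6.23 and 4.35 FPKM. The gene lies on chromosome 2 at 161308038 to 161411717 on the plus strand (GRCh38). ESR1, which encodes ERα and lies on chromosome 6 at 151656691 to 152129619 on the plus strand, fell by a smaller amount, from 52.9 ± 4.53 to 42.1 ± 4.75 FPKM. The log2 changes were -3.13 ± 0.11 (SE) for PSMD14 and -0.33 ± 0.08 for ESR1, with adjusted p of 7.06e-11 and 0.00356 (limma, Benjamini-Hochberg). For neither gene did the 3 and 3 libraries overlap, and an exact two-sided permutation test gave p = 0.1 for each, the smallest that 3 against 3 libraries can give. The change of ESR1 was -0.51 after a correction for transcript length and GC content. The ESR1 transcript also holds 1 copy of the 7-base word GTTGGTA, in the 3' UTR in exon 10 of 10 at 152101622 to 152101628. The 788 genes with this word in the 3' UTR had a mean log2 shift of -0.21 after adjustment for length and base composition. The shift was 0.02 in the 10076 genes with the word in neither the 3' UTR nor the coding part.

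**Figure D1:**
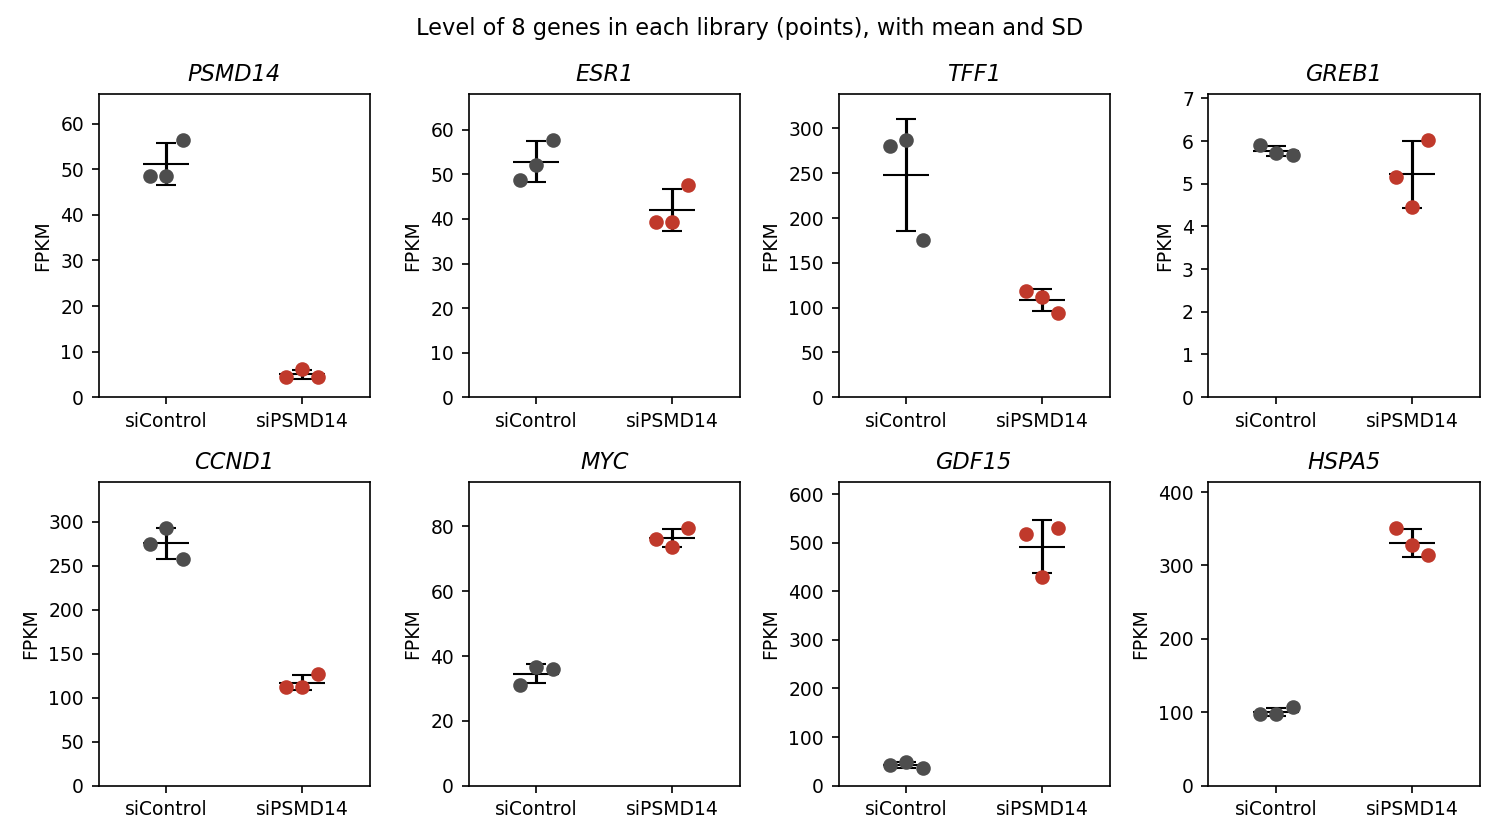
FPKM of 8 genes (one panel each, vertical axis in FPKM from 0) in the 3 siControl and 3 siPSMD14 libraries. Points are libraries, and the horizontal bar and whiskers are the mean and SD. PSMD14 lay between 48.5 and 56.5 FPKM in siControl and between 4.35 and 6.23 FPKM in siPSMD14, while the GREB1 libraries of the groups overlapped.

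Beyond the targeted gene, the largest rises on the log2(FPKM + 1) scale included genes of stress responses and inflammation. GDF15, a stress-induced secreted cytokine of the TGF-beta family, rose from 42.1 ± 6.19 to 492 ± 54.6 FPKM. The AP-1 subunit gene FOSL1 rose from 0.850 ± 0.0173 to 19.1 ± 1.80 FPKM, and the chemokine gene CXCL8 from 0.537 ± 0.166 to 14.4 ± 0.710 FPKM. The cytokine gene IL6 rose from 0.213 ± 0.0814 to 7.20 ± 1.04 FPKM, and the fibrinogen chain gene FGB from 0.0967 ± 0.00577 to 9.83 ± 1.36 FPKM. EPDR1 and ROM1 rose by 3.01 and 2.99 on the log2 scale. The chaperone gene HSPA1A, the heme oxygenase gene HMOX1 and the stress-induced transcription factor gene ATF3 rose by 2.78, 2.64 and 2.60. CXCL8 rose although its 3' UTR holds 1 GTTGGTA word.

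Apart from PSMD14, the 9 largest falls on that scale were INHA, SLC25A30, DEGS2, PSCA, PKP1, SFT2D1, GALNT7, LRRC26 and OBSL1. INHA, which encodes the inhibin alpha subunit, fell from 58.8 ± 8.43 to 8.05 ± 0.737 FPKM. The mitochondrial carrier gene SLC25A30 fell from 20.3 ± 2.71 to 4.38 ± 0.257 FPKM, and the sphingolipid desaturase gene DEGS2 from 9.12 ± 0.777 to 1.68 ± 0.211 FPKM. PSCA, which encodes a GPI-anchored surface protein, and PKP1, which encodes the desmosomal protein plakophilin-1, had log2 changes of -1.85 each. SFT2D1, GALNT7, LRRC26 and OBSL1 had log2 changes of -1.83, -1.79, -1.74 and -1.70. SLC25A30 and SFT2D1 each held 1 GTTGGTA word in the 3' UTR and GALNT7 held 2. That word occurred in 37 of the 148 genes with a searched 3' UTR that fell at least 2-fold (25%), against 6.98% of all 11294 genes searched. Among all searched genes that passed the threshold, 305 of the 3340 that fell and 188 of the 3787 that rose held it.

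Over all genes tested, 7461 changed (limma, adjusted p under 0.05, Benjamini-Hochberg), of which 3955 rose and 3506 fell. A change of at least 2-fold was reached by 365 that rose and 154 that fell. With a correction for transcript length and GC content, chosen after the data were seen, 3759 rose and 4291 fell. The libraries differed in how their values ran with transcript length. The median deviation from the 6-library mean in the shortest 20% of genes went from 0.12 in siControl 1 to -0.14 in siPSMD14 3, and every siControl library lay above every siPSMD14 library there.

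**Figure D2:**
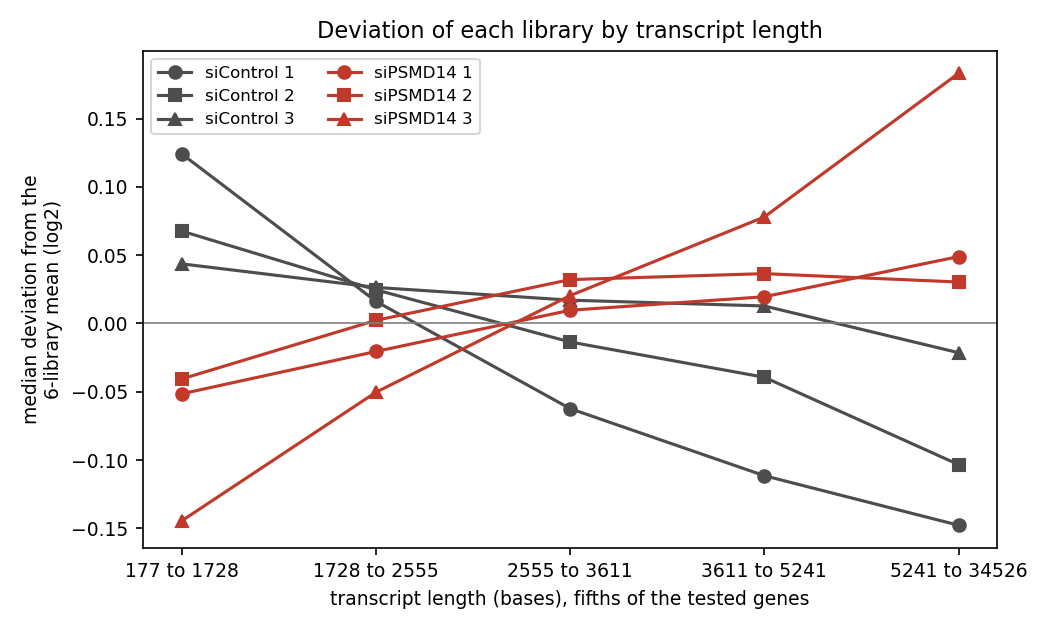
Median deviation of each library from the mean of the 6 libraries (vertical axis, log2 units) in the tested genes divided into bins of 20% by transcript length in bases (horizontal axis). Grey lines are siControl and red lines siPSMD14, with 1 marker shape per replicate number. In the shortest 20% the 3 siControl libraries lay between 0.04 and 0.12 and the 3 siPSMD14 libraries between -0.14 and -0.04.

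Most other subunit genes of the 19S particle and the 20S core of the proteasome rose while PSMD14 fell. All 18 tested genes of the 19S regulatory particle other than PSMD14 rose, from 0.21 for PSMD7 to 1.08 for the ATPase subunit gene PSMC4, and the list passed the set test (camera, adjusted p = 6.09e-08). With an estimated correlation the list did not pass (adjusted p = 0.312 with an estimated correlation). PSMD11 rose from 27.9 ± 0.386 to 56.5 ± 0.951 FPKM, and PSMC3 from 85.5 ± 5.83 to 182 ± 8.95 FPKM. Of the 14 genes of the 20S core, the barrel that holds the proteolytic sites, 11 rose and none fell (camera, adjusted p = 0.00347; adjusted p = 0.613 with an estimated correlation). PSMB4, PSMB2 and PSMA5 rose by 0.82, 0.59 and 0.60. Both lists gave the same counts adjusted over the list alone. Among 36 tested genes for assembly chaperones, activators and the NFE2L1 pathway, which controls proteasome genes, 18 rose and 9 fell, also when adjusted over the list alone. That list did not pass (camera, adjusted p = 0.0856; adjusted p = 0.447 with an estimated correlation), but it passed with quantile normalization (adjusted p = 0.0279), without siPSMD14 3 (adjusted p = 0.0405) and without both siControl 1 and siPSMD14 3 (adjusted p = 0.0297). In these settings it did not pass with an estimated correlation (adjusted p = 0.282, 0.391 and 0.529 with an estimated correlation). Its members with the smallest p were the shuttle factor gene RAD23A, which rose from 88.2 ± 3.41 to 277 ± 12.4 FPKM, and the polyubiquitin gene UBC, which rose from 650 ± 14.5 to 1729 ± 115 FPKM.

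Most tested genes of 3 protein-damage and stress pathways rose. Of 26 heat shock genes, targets of HSF1 and cytosolic chaperones, 17 rose and 2 fell (18 and 2 adjusted over the list alone; camera, adjusted p = 3.30e-05; adjusted p = 0.323 with an estimated correlation). HSPA1A rose from 172 ± 16.7 to 1183 ± 52.96 FPKM, HSPA1B from 237 ± 21.8 to 1160 ± 53.7 FPKM, and HSPB8 by 2.33. HSPA1A and HSPA1B are near-identical copies, so the split of fragments between them is uncertain. Of 27 endoplasmic reticulum chaperones and targets of XBP1 and ATF6, 22 rose and 2 fell, with the same counts adjusted over the list alone (camera, adjusted p = 3.43e-06; adjusted p = 0.267 with an estimated correlation). The chaperone gene HSPA5 rose from 100.5 ± 5.36 to 331 ± 18.6 FPKM, and DNAJB9 and HYOU1 rose by 1.79 and 1.19, while XBP1, which encodes a transcription factor of this response, fell by 0.98. Of 27 targets of ATF4 and DDIT3, 20 rose and 4 fell, again with the same counts adjusted over the list alone (camera, adjusted p = 5.00e-06; adjusted p = 0.267 with an estimated correlation). ATF3, PPP1R15A, which encodes a phosphatase subunit that restores translation, and DDIT3, which encodes the transcription factor CHOP, rose by 2.60, 2.45 and 2.13.

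Targets of the antioxidant response mostly rose, and autophagy genes were mixed. Of 23 targets of NFE2L2, the transcription factor of the antioxidant response, 15 rose and 2 fell, or 16 and 2 adjusted over the list alone (camera, adjusted p = 0.000135; adjusted p = 0.267 with an estimated correlation). HMOX1 rose from 43.3 ± 4.14 to 274 ± 21.4 FPKM, and OSGIN1 and PIR rose by 2.50 and 1.87. Of 32 autophagy receptors and lysosomal genes, 13 rose, 6 fell and 13 did not pass, with the same rises and falls adjusted over the list alone. That list passed the set test (camera, adjusted p = 0.022; adjusted p = 0.311 with an estimated correlation), with a median change of 0.11. GABARAPL1 and ULK1, genes of autophagosome formation, rose by 1.75 and 1.61, and the receptor gene SQSTM1 rose from 192 ± 12.1 to 458 ± 11.2 FPKM.

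Most tested p53 targets, immediate early genes and inflammatory genes rose as well. Of 37 p53 targets, 28 rose and 2 fell (29 and 2 adjusted over the list alone; camera, adjusted p = 6.09e-08; adjusted p = 0.267 with an estimated correlation). CDKN1A, the gene of the CDK inhibitor p21, rose from 54.0 ± 2.19 to 259 ± 15.5 FPKM, and BTG2 and GDF15 rose by 2.12 and 3.52. The list of 12 CDK inhibitors and RB family genes, which also holds CDKN1A and BTG2, had 4 rises and 4 falls (5 and 4 adjusted over the list alone) and did not pass (camera, adjusted p = 0.594). Of 22 immediate early genes, 17 rose and 1 fell, with the same counts adjusted over the list alone (camera, adjusted p = 1.21e-06; adjusted p = 0.323 with an estimated correlation). FOSL1, ATF3 and ZFP36, the gene of an mRNA decay factor, rose by 3.44, 2.60 and 1.65. Of 17 NF-kB targets and inflammatory mediators, 15 rose and none fell, also adjusted over the list alone (camera, adjusted p = 1.16e-05; adjusted p = 0.311 with an estimated correlation). CXCL8, IL6 and RELB rose by 3.33, 2.75 and 1.29. Without siControl 1 and siPSMD14 3, the libraries at the ends of the length trend, 13 NF-kB genes were tested. Of these, 9 rose and none fell (camera, adjusted p = 0.00103, and adjusted p = 0.441 with an estimated correlation). The filter left out CXCL8 and IL6 there, which were under 1 FPKM in every siControl library. Without siPSMD14 1, 2 or 3 alone, 13 were also tested, of which 11, 11 and 10 rose. The lower count of tested genes is therefore not tied to the length trend.

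Most tested genes of 2 cell cycle lists fell. Of 48 genes of G2/M and mitosis, 38 fell and 1 rose, with the same counts adjusted over the list alone (camera, adjusted p = 1.64e-08; adjusted p = 0.323 with an estimated correlation). The mitotic kinase gene AURKA fell from 108 ± 3.03 to 63.6 ± 3.01 FPKM, and CDC25B and KIF23 had log2 changes of -0.67 and -0.68. Of 44 E2F targets of G1/S and DNA replication, 26 fell and 9 rose (26 and 10 adjusted over the list alone; camera, adjusted p = 0.000324; adjusted p = 0.589 with an estimated correlation). CCND1, which encodes the G1 cyclin D1, fell from 275 ± 17.1 to 117 ± 8.06 FPKM. The helicase subunit gene MCM2 and the folate enzyme gene DHFR, which holds 1 GTTGGTA word in its 3' UTR, had log2 changes of -0.79 and -1.07.

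Genes induced through ERα included both rises and falls, as did the 11867 tested genes as a whole, of which 3955 rose and 3506 fell. Of 51 tested genes of the estrogen-induced list, 21 rose, 17 fell and 13 did not pass (22 and 17 adjusted over the list alone), and the set test did not pass (camera, adjusted p = 0.594; adjusted p = 0.788 with an estimated correlation). The rotation test fry, which asks whether the genes moved on balance in 1 direction without comparing them with other genes, passed upward (adjusted p = 0.00538). The list median was 0.09, and it was -0.02 after the correction for length and GC content. TFF1, a secreted peptide gene long used as an ERα target, fell from 248 ± 62.7 to 108 ± 12.3 FPKM (log2 change -1.16 ± 0.15 SE, adjusted p = 1.35e-05, limma). CCND1, which this list also holds, fell by 1.23, whereas MYC rose from 34.5 ± 2.99 to 76.4 ± 2.84 FPKM. The chaperone gene HSPB8 rose by 2.33 and the protease gene PRSS23 by 1.56; the 3' UTR of PRSS23 holds 1 copy of another word, TCGGAGA, whose 209 carriers had a mean adjusted shift of 0.26. GREB1 was at 5.76 ± 0.121 FPKM in siControl and 5.22 ± 0.786 FPKM in siPSMD14 and did not pass (log2 change -0.13, adjusted p = 0.257, limma). It passed with quantile normalization (-0.23, adjusted p = 0.0436) and with the correction for length and GC content (-0.33, adjusted p = 0.001), and its 3' UTR holds 1 TCGGAGA word. PGR, the progesterone receptor gene, was listed at 0 in 5 libraries and at 0.01 FPKM in siPSMD14 1, and was not tested.

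Of 12 tested genes repressed through ERα, 3 rose and 5 fell, also adjusted over the list alone, and the list did not pass (camera, adjusted p = 0.669; adjusted p = 0.847 with an estimated correlation). BTG2 rose from 25.5 ± 0.986 to 114 ± 5.16 FPKM, while the BCL2 family gene BMF fell from 8.82 ± 0.497 to 2.26 ± 0.174 FPKM. Of 32 luminal transcription factors, ERα cofactors and keratins, 13 rose and 14 fell, also adjusted over the list alone (camera, adjusted p = 0.498; adjusted p = 0.695 with an estimated correlation). The median of that list was 0.04 and its mean -0.13. XBP1 fell from 791 ± 49.2 to 401 ± 14.97 FPKM, and the keratin gene KRT18 from 4873 ± 514 to 1743 ± 116 FPKM. The change of KRT18 was -1.48, or -0.97 with quantile normalization, and fragments of its processed pseudogenes cannot be separated here.

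**Figure D3:**
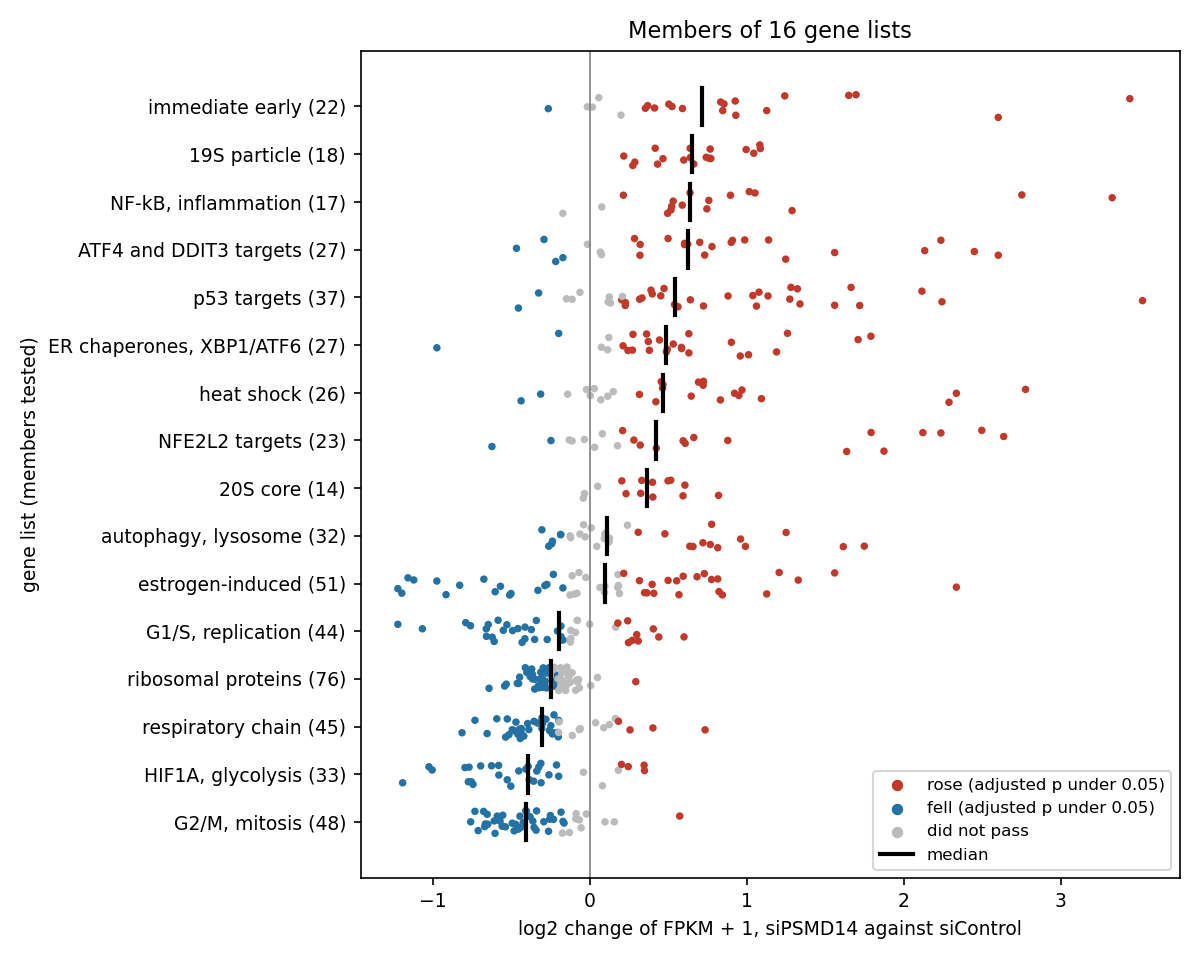
Log2 change of FPKM + 1 (horizontal axis, siPSMD14 against siControl) of each tested member of 16 gene lists (vertical axis, number of tested members in brackets). Points are genes, coloured by whether they rose, fell or did not pass, and black bars are list medians. All 18 members of the 19S list lay above 0, 38 of 48 G2/M genes fell, and the estrogen-induced list had 21 rises and 17 falls.

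Most of the glycolytic and respiratory chain genes tested fell, and 43 of 76 ribosomal protein genes did. Of 33 HIF1A targets and glycolytic genes, 26 fell and 4 rose (26 and 5 adjusted over the list alone; camera, adjusted p = 5.00e-06; adjusted p = 0.311 with an estimated correlation). HK1, the gene of a hexokinase, fell from 84.5 ± 2.68 to 36.3 ± 0.146 FPKM, LDHA, the gene of a lactate dehydrogenase subunit, from 638 ± 14.6 to 313 ± 22.1 FPKM, and BNIP3 from 162 ± 6.03 to 95.2 ± 2.05 FPKM. Of 45 nuclear-encoded respiratory chain genes, 32 fell and 4 rose (33 and 4 adjusted over the list alone; camera, adjusted p = 3.30e-05; adjusted p = 0.613 with an estimated correlation). NDUFB10 fell from 260 ± 26.5 to 147 ± 7.18 FPKM and ATP5MC3, which holds 1 GTTGGTA word in its 3' UTR, from 73.0 ± 3.20 to 45.9 ± 2.11 FPKM, while NDUFS2 rose by 0.73. Of the 76 cytosolic ribosomal protein genes, 43 fell and 1 rose, also adjusted over the list alone (camera, adjusted p = 4.38e-06; adjusted p = 0.695 with an estimated correlation; adjusted p = 0.0620 with quantile normalization). RPL24, RPL27A and RPL38 had log2 changes of -0.53, -0.40 and -0.54, and fragments of ribosomal pseudogenes cannot be separated here.

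Short transcripts as a class were lower in siPSMD14, with a median change of -0.17 in the shortest 20% of tested genes and 0.18 in the longest 20%. The median transcript length was 922 bases for the ribosomal list and 1141 bases for the respiratory chain list, both within the shortest 20%, which reached 1728 bases. For the ribosomal list the call was lost with quantile normalization, where 30 genes fell and 9 rose around a median of -0.09 (camera, adjusted p = 0.062). The ribosomal genes that fell numbered 26 without siControl 1, 27 without siPSMD14 3 and 21 without both, where the median was -0.14 against -0.25 with all libraries (camera, adjusted p = 0.00122; adjusted p = 0.529 with an estimated correlation). Without both, 23 respiratory chain genes fell, with a median of -0.18 against -0.30 (camera, adjusted p = 0.000903; adjusted p = 0.441 with an estimated correlation).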

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

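The length and GC correction, the omission of carriers of GTTGGTA or TCGGAGA, the omission of siControl 1 with siPSMD14 3, and the estrogen-induced list without stress-list members were chosen after the data were seen. The omission of carriers took out genes with either word in the 3' UTR, and also genes with no 3' UTR sequence. PSMD14, ESR1 and the count of changed genes kept their direction and their side of the threshold under every alternative run, apart from the minimum change; ESR1 holds GTTGGTA and was itself left out with the carriers. With 1 library left out, 6578 to 7430 genes changed, PSMD14 lay between -3.28 and -3.06, ESR1 between -0.41 and -0.26, the estrogen-induced median between 0.08 and 0.16, and 15 or 16 lists passed. A 2-fold minimum left 519 genes (365 rose, 154 fell). Quantile normalization gave 3585 rises and 3969 falls (47.5% rises against 53.01%), and the length and GC correction 3759 and 4291. Without the libraries at the ends of the length trend 6030 genes changed. Without the word carriers and the genes with no 3' UTR sequence, 6692 of 10588 changed. A word in the coding part did not lead to omission. Genes with GTTGGTA or TCGGAGA in the coding part alone had mean adjusted shifts of -0.11 and 0.14. No list passed camera with an estimated correlation (0 against 15; 4 had an unadjusted p under 0.05) and 29 passed fry, including the estrogen-induced list (median 0.094, adjusted p = 0.00538); fry does not compare a list with other genes.

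Lists that had not passed changed direction in some settings, and the cause was not tested. The replication histone list turned up with no filter (0.11), after the length and GC correction (0.11), without the word carriers (0.26) and without the end libraries (0.038), and by fry on the same median of -0.073. It ran from -0.14 to 0.025 with 1 library left out, turning up without siControl 1. The interferon list turned down with a filter at 5 (median 0.044) and ran from 0.019 to 0.14 with 1 library left out, turning down without siPSMD14 1. Directions here are those of camera, which can differ in sign from the median. The basal list ran from -0.019, without siPSMD14 3, to 0.14 with 1 left out and was -0.069 without the end libraries. Some medians changed sign while camera kept its direction. The basal median was -0.033 with quantile normalization and -0.060 after the length and GC correction. The CDK inhibitor median (0.14) was -0.015 after that correction and -0.032 without the end libraries, where the luminal median (0.041) was -0.0097. The BCL2 family median (-0.042) was 0.082 with no filter and with a filter at 5, 0.16 without the word carriers and 0.0030 without siControl 3. The estrogen-induced median was -0.015 after the length and GC correction. The small RNA list turned down, to -0.063, after the length and GC correction. The estrogen-repressed list turned up by fry (median -0.068). Its median ran from -0.13 to 0.067 with 1 library left out and was 0.035 with a filter at 5, while the direction of camera stayed down.

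The data did not settle whether same-numbered libraries were paired. Their deviations correlated at 0.34 for number 1, -0.08 for number 2 and 0.42 for number 3. Libraries of unlike number correlated at -0.46 to 0.18, so numbers 1 and 3 lay above all of these and number 2 did not. The library siPSMD14 2 correlated best with siControl 1. With the replicate number as a block 8061 genes changed, 4253 up and 3808 down, and no list or named gene gained or lost its call. Of the named genes, CD68 lost its call in 8 settings. With a pseudocount of 0.1 the changes of genes near 0 grew, to 5.65 for FGB and 4.57 for IL6. The fit for count data and its filters were not run, because the values are not counts. At 20370000 to 21140000 fragments per library, the depths inferred with FPKM as the unit, genes under 1 FPKM rest on few fragments.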

Other observations

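The tests of explanations in this part, apart from that of coding sites, were chosen only after the result they bear on was seen. Several gene groups that did not pass the set test held genes with clear changes in both directions. Of all 11867 tested genes 3955 rose and 3506 fell. Rises beside falls were therefore usual for a group of genes here, and the counts below are not a trait of these groups. Among 24 BCL2 family and caspase genes, 10 rose and 7 fell (10 and 8 adjusted over the list alone; camera, adjusted p = 0.691), with a median of -0.04 and a mean of 0.12. The executioner caspase gene CASP7 rose from 5.44 ± 0.781 to 23.2 ± 0.901 FPKM and the p53-responsive gene BBC3 by 1.72. Among 27 JAMM proteases and deubiquitinases or ubiquitin ligases described for ERα, 10 rose and 7 fell, also adjusted over the list alone (camera, adjusted p = 0.594). The ubiquitin ligase gene MDM2 rose from 15.8 ± 1.12 to 41.5 ± 2.35 FPKM, and the translation factor gene EIF3F, which holds 1 GTTGGTA word, by 1.04. Of 28 interferon-stimulated genes, 10 rose and 8 fell, also adjusted over the list alone (camera, adjusted p = 0.564). IFIT2, which holds 1 GTTGGTA word, rose from 0.380 ± 0.0700 to 2.78 ± 0.236 FPKM, and IFITM1 fell from 29.2 ± 3.19 to 11.3 ± 2.23 FPKM. Of 12 genes of MHC class I presentation, 7 rose and 3 fell, also adjusted over the list alone (camera, adjusted p = 0.411). PSMB9, an immunoproteasome subunit gene, fell from 2.22 ± 0.165 to 1.01 ± 0.215 FPKM while the peptide transporter gene TAP2 rose by 0.49.

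Zinc, sterol and chromatin genes also split. All 5 tested genes of the metallothionein list changed, 2 up and 3 down, also adjusted over the list alone (camera, adjusted p = 0.594). MT2A fell from 175 ± 24.8 to 93.4 ± 6.77 FPKM, while MTF1, the gene of the zinc-responsive transcription factor, rose by 0.75 and holds 1 copy each of GTTGGTA and TCGGAGA. Of 25 cholesterol synthesis genes and SREBF2 targets, 11 fell and 5 rose, also adjusted over the list alone (camera, adjusted p = 0.215). The receptor gene LDLR rose from 16.8 ± 1.11 to 35.05 ± 2.47 FPKM, and the sterol desaturase gene SC5D, which holds 1 GTTGGTA word, fell by 0.78. Of 34 ribosome biogenesis genes and MYC targets, 11 rose and 5 fell (11 and 4 adjusted over the list alone; camera, adjusted p = 0.377), with TCOF1 up by 1.11 and MYC by 1.13. Of 12 replication histone genes, 4 rose and 4 fell (5 and 4 adjusted over the list alone; camera, adjusted p = 0.833), with HIST1H2BD up by 0.71 and HIST1H4C at -1.13. Of 13 small RNA pathway genes, 6 rose and 3 fell, also adjusted over the list alone (camera, adjusted p = 0.560). DROSHA rose by 0.97 and AGO1, which holds 1 GTTGGTA word, by 0.71, or by 0.42 after the correction for length and GC content. Of 27 mesenchymal genes and TGF-beta targets, 13 rose and 8 fell (13 and 9 adjusted over the list alone; camera, adjusted p = 0.598), with TGFBI up by 1.52 and ID2 at -0.96. Of 11 basal markers, 4 rose and 2 fell, also adjusted over the list alone (camera, adjusted p = 0.564), with CD44 and LAMB3 up by 0.93 and 0.98. Of the fibroblast, endothelial and leukocyte markers 3 were tested, of which 2 rose and none fell, also adjusted over the list alone (camera, adjusted p = 0.546). These were CD8A, from 0.707 ± 0.0321 to 1.27 ± 0.142 FPKM, and CD68, from 1.16 ± 0.102 to 1.54 ± 0.241 FPKM. The CD68 call was lost without siControl 1, siControl 2, siPSMD14 1 or siPSMD14 2, with adjusted p from 0.0859 to 0.210 (limma). Metallothionein and histone genes, and IFITM1, have near-identical relatives, so their share of fragments is uncertain.

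The 6 libraries can be split into 3 and 3 in 10 ways, and 1 split, the real one, gave 7461 changed genes. The highest of the other splits gave 0 by limma (at most 272 genes at an unadjusted p under 0.05). Every other split mixes siControl and siPSMD14 libraries on both sides. A large difference between the groups then widens the spread within each side, so these low counts say little about chance. With 10 splits, a share under 0.05 cannot be reached.

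Genes carrying either of 2 words of 7 bases in the 3' UTR shifted in opposite directions. Among all 16384 words, GTTGGTA (788 genes) had the lowest z and TCGGAGA (209 genes) the highest, in each of the 9 pairs of a siControl and a siPSMD14 library. Both words also occur in exon 7 of 12 of the PSMD14 messenger RNA, in the coding part, at 161371189 to 161371195 and 161371269 to 161371275 on chromosome 2. That message holds 1762 of the 16384 words, so the presence of a word in it may be chance. Genes with GTTGGTA followed by A had a mean adjusted shift of -0.29 ± 0.03 (SE, 259 genes), and the other full sites -0.17 ± 0.02 (529 genes). Genes with no full site but its last 6 bases followed by A were at -0.017 ± 0.013 (930 genes). Those with its last 6 bases alone were at -0.005 ± 0.011 (1438 genes). The 95% intervals of these last 2 classes included 0. Genes with no match of 6 bases were at 0.02 ± 0.01 (8138 genes). TCGGAGA occurred in 23 of the 348 searched genes that rose at least 2-fold (6.61%), against 1.85% of all searched. Among all searched genes that passed the threshold, 122 of the 3787 that rose and 33 of the 3340 that fell held TCGGAGA.

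A candidate explanation for GTTGGTA is seed pairing, in which bases near the start of an siPSMD14 strand pair with untargeted messages as a microRNA would. The word's z was -12.99, against -5.08 for the next of 1762 words in the PSMD14 messenger RNA and -4.72 as the lowest of 100 permutations, and genes with the word in the coding part alone shifted less (-0.11, 95% interval -0.15 to -0.07) than those with a 3' UTR site (-0.25 to -0.18). Length, GC and base composition as the cause are argued against by the other 139 words of the same bases, whose lowest z was -2.95. For TCGGAGA, with z = 8.17 against at most 4.83 in permutations, loss of pairing by an siControl strand may play the same part, but the siRNA sequences were not used here and an endogenous microRNA was not tested for either word. Whether the site lowered ESR1 cannot be told apart from an effect of PSMD14 loss, because 24.5% of the 721 genes with 1 site and 10.8% of genes without one had an adjusted change at or below that of ESR1 (-0.47).

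The lower ribosomal, respiratory chain and glycolytic genes could reflect the trend of the libraries with transcript length, or scaling shifted by a few abundant genes, whose top 10 held 8.04% to 9.34% of FPKM in siControl and 6.29% to 6.74% in siPSMD14. After the correction for length and GC content the ribosomal median was -0.15 (95% bootstrap interval over genes -0.18 to -0.09). The respiratory chain and glycolytic medians were -0.21 (-0.26 to -0.16) and -0.41 (-0.63 to -0.33). Each list still passed camera at the preset correlation. For the ribosomal and respiratory chain lists this argues against the trend as the whole cause. The glycolytic list had a median transcript length of 2827 bases and a median of -0.39 before the correction. Tested genes of 2555 to 3611 bases had a median change of 0.04. At that length the trend gave no fall to remove, so passing after the correction does not test it for this list. With an estimated correlation none of the 3 lists passed (adjusted p = 0.810, 0.611 and 0.389 with an estimated correlation). Under whichever of quantile and median-ratio scaling lay nearer 0, the respiratory chain and glycolytic medians were -0.23 and -0.40 and passed at the preset correlation, which argues against scaling as the whole cause for those lists (adjusted p = 0.470 and 0.326 with an estimated correlation). The ribosomal list had a median of -0.091 and did not pass with quantile normalization (camera, adjusted p = 0.0620), but had a median of -0.27 and passed with median-ratio scaling (camera, adjusted p = 2.48e-05; adjusted p = 0.757 with an estimated correlation). A smaller share of the top 10 in siPSMD14 would raise the other genes there, not lower them. Median-ratio scaling also left the ribosomal median no nearer 0 (-0.27 against -0.25 without it). Both argue against a shift of each library's scale by a few abundant genes. Quantile normalization also changes the shape of each library's distribution. An effect of that shape on the ribosomal list cannot be told apart from a lower level of ribosomal messages in siPSMD14. An effect of PSMD14 loss stays open for all of these lists as a hypothesis.

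The estrogen-induced list moved both ways, and rises of members that also answer to stress could account for this. Its 5 members shared with the stress, p53, inflammatory or immediate early lists were MYC, HSPB8 and FKBP4, which rose, and XBP1 and STC2, which fell; FKBP4 and STC2 are named because they belong to this group, after their values were seen. Outside these, 18 members rose and 15 fell. With 5 shared members and 21 rises in the list, most rises had to lie outside whatever the values, so stress as a source of the rises cannot be told apart from other causes by this count. After the correction for length and GC content 22 members rose and 19 fell. Most lists would keep both directions after the correction, so this count cannot tell the length trend apart from other causes. Of all 11711 genes tested after the correction, 3759 rose and 4291 fell. Other regulation of these genes, through ERα or not, was not tested.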
